A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

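RNA was measured by high-throughput sequencing of polyadenylated RNA in 9 libraries, with 3 biological replicates each of wild type BY4742, pil1Δ and seg1Δ nce102Δ pil1Δ yeast, per the labels. Per the labels' protocols, cells grown for 24 h at 28 °C in synthetic complete medium were washed in 10 mM fluoride and azide and lysed with glass beads, and RNA was purified on columns, treated with DNase and selected for poly(A). The submitters' processing notes name GSNAP, DESeq2 and DESeq and the genome build R64, without versions or roles. The counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

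The first deposited table holds a signal for each of 6215 genes and 9 libraries that is a read count divided by 1 size factor per library. The values themselves showed this: in each column 100% of values were whole multiples of the smallest value above 0, at a tolerance of 1e-06. Whole reads recovered in this way came to between 21064051 and 27014469 per library, with size factors between 0.791 and 1.34. The second deposited table holds log2 values of the same genes and libraries after a transformation whose kind is not given in the sources used here, and it was used as an alternative.

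The main test had been set before the data were examined, with a branch for raw counts and a branch for normalized values. The values were normalized, so the second branch applied: limma (lmFit, then eBayes with trend and robust) on log2(value + 1), with all 9 libraries in the fit, group means only, and contrasts between groups. Genes with a mean of at least 10 normalized reads over all libraries were tested, 5886 in all, and 329 were left out. P-values were two-sided and adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the tests rest on the spread pooled over genes.

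A set of 40 gene lists was fixed before the data were examined, and 39 with at least 4 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move on balance one way and compares them with no other genes. Deleted genes were left out of the list tests. Lists of ribosomal proteins were drawn by symbol.

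The text names genes by a rule fixed at the same time. It takes the deleted and marker genes, the genes beside them, every measured eisosome gene, and up to 4 members of each list with the smallest p. In each contrast it also takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 and with libraries of the 2 groups not overlapping, which chance gives for 10% of unchanged genes. A few further genes, named because a count was small or a list member fell or rose against its list, were chosen after their values were seen: UBI4, SNO1, YMR1, RPP1, THI4 and, in the closing part, CRH1, PIR3, YEH1, TIP1 and the genes at the ends of chromosomes I and III.

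Gene coordinates and sequence came from the R64 reference annotation, in which 6212 identifiers were found and 3 were not. For 884 genes without a symbol, the systematic name was used. Genes with another gene at least 90% identical over at least 50% of the length (470 genes) or overlapping another gene (166 genes) were marked as uncertain.

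Replicates of 1 group differed by far more than sampling noise (chi-square per degree of freedom 35.0 to 382.8), so no library was treated as a second deposit of another. The labels number the replicates alike in each group. Deviations from the group mean of same-numbered wild type and pil1 libraries correlated at 0.639, 0.833 and 0.579 for numbers 1 to 3, so those numbers were treated as pairs. The pairing comes from this check and not from the labels. The fit with the replicate number as a block was an alternative.

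Alternatives fixed before the data were examined were TMM scaling, the transformed table, no filter, a minimum mean of 50, a pseudocount of 5, only the groups compared, the replicate block, and each library left out in turn. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test and DESeq2 on the recovered reads, scaling by total reads, wild type 1 and triple mutant 1 left out together, each pair of same-numbered wild type and pil1 libraries left out together, the block with only the groups compared, and a per-library trend on GC content and coding length removed with and without the block. Comparisons against the shared wild type were set beside 100 simulations of unchanged groups, drawn without the pairing, and the overlap of the comparisons that share the triple mutant beside 50 simulations each of unchanged groups and of pil1 equal to wild type.

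The tests were tested on simulated data drawn from the libraries' means and depths. For pil1 against wild type, with 5886 genes, limma recovered 53.7% of genes changed 1.5-fold, 88.1% changed 2-fold and 97% changed 4-fold, with 2 false calls of 161. For the triple mutant against wild type, it recovered 44.8%, 89.6% and 97%, with 6 false calls of 160. DESeq2 made 13 false calls of 183 and 22 of 188 on the same simulated data. In each simulated comparison 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. The real triple mutant had 60.9% of genes called against wild type, so these rates may not hold for it. The simulated genes were drawn independently, so these simulations do not test camera on lists whose members are correlated, and the estimated correlation within a list reached 0.857 in the data. The floor of 3 reads covers counting error only, and molecular identifiers are not given in the sources used here. Confidence intervals of fold changes come from limma's estimate of the spread between replicates.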

Results

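Polyadenylated RNA was sequenced from 3 haploid strains of budding yeast, with 3 biological replicates each. The wild type was BY4742, a MATα laboratory strain. The pil1 strain lacked PIL1, which encodes a main structural protein of eisosomes, the protein assemblies that shape furrow-like membrane compartments beneath the plasma membrane. The triple mutant lacked PIL1, SEG1 and NCE102 together. Seg1 is an eisosome organiser, and Nce102 is a membrane protein of the same compartment. All strains had been grown for 24 h in synthetic complete medium at 28 °C. The series set out to compare gene expression between the wild type and these deletion strains. Library depth, recovered as whole reads from the normalized values, was 26381388, 25137073 and 24932904 reads in wild type replicates 1 to 3, 25795877, 27014469 and 22430652 in pil1, and 23671868, 22642510 and 21064051 in the triple mutant. The first principal component held 81.3% of the variance and placed the triple mutant libraries at 44.7 to 57.5, against -27.8 to -20.7 for the other 6 libraries.

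The deleted genes followed the genotypes in all 9 libraries. PIL1 (YGR086C, chromosome VII, 649598 to 650617, R64) had 19200 ± 2940 normalized reads in wild type (mean ± SD, n = 3), 114 ± 2.94 in pil1 and 93.7 ± 5.42 in the triple mutant, which left 0.595% and 0.488% of the wild-type level. SEG1 (YMR086W, chromosome XIII, 439208 to 442090) had 6630 ± 526 normalized reads in wild type, 6410 ± 394 in pil1 and 18.3 ± 7.82 in the triple mutant. NCE102 (YPR149W, chromosome XVI, 829918 to 830439) fell from 96500 ± 11500 in wild type to 204 ± 56.4 in the triple mutant, and had 90800 ± 12800 in pil1. The recovered reads behind these values were 133, 149 and 118 on PIL1 in pil1 replicates 1 to 3. In the triple mutant they were 79, 87 and 79 on PIL1, 24, 13 and 11 on SEG1, and 122, 223 and 189 on NCE102.

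The strains also differed at a marker gene outside the 3 deletions. The genotypes listed a lys2 deletion in wild type and pil1, and LYS2 as present in the triple mutant. LYS2 (YBR115C, chromosome II, 469748 to 473926), which encodes the aminoadipate reductase of lysine synthesis, had 0 reads in all 6 wild type and pil1 libraries and 30700 ± 5490 normalized reads in the triple mutant. Against a floor of 3 reads per library this was at least 11100-fold higher than wild type and at least 10400-fold higher than pil1, where the floor covers counting error only. HIS3, listed with the his3Δ1 allele in all strains, had 8990 ± 813 normalized reads in wild type, 8900 ± 382 in pil1 and 4580 ± 1370 in the triple mutant, and was 2.03-fold lower in the last than in wild type (adjusted p = 0.00238 by limma). MET17, the gene also called MET15, fell from 25500 ± 2390 in wild type to 14800 ± 3880 in the triple mutant (log2 fold change -0.81, SE 0.19, adjusted p = 0.00501 by limma). MET17 overlaps YLR302C on the opposite strand by 12 bases, and its level is uncertain to that extent.

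**Figure D1:**
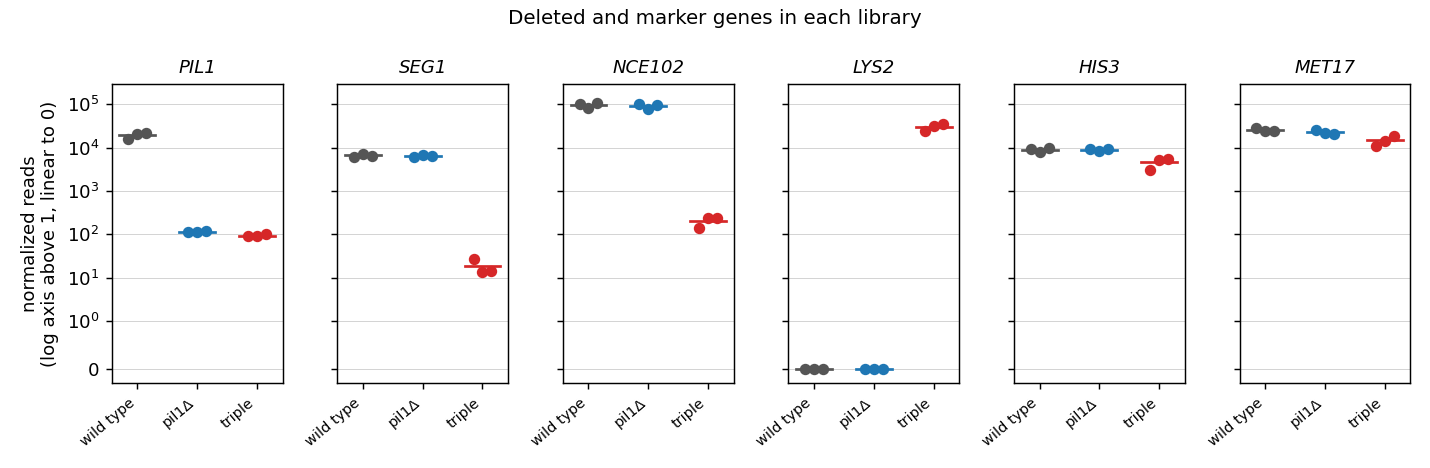
Normalized reads (vertical axis, symmetric log scale) of PIL1, SEG1, NCE102, LYS2, HIS3 and MET17 in each of the 9 libraries, grouped by strain, 1 point per library. PIL1 lies at 111 to 116 in pil1 and 89.9 to 99.9 in the triple mutant, and LYS2 lies at 0 outside the triple mutant.

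Deletion of PIL1 alone left the transcript levels of single genes close to wild type. Of 5886 genes tested, limma called PIL1 itself lower (log2 fold change -7.37, SE 0.12, adjusted p = 1.78e-09) and 0 genes higher. At an unadjusted p under 0.05 it listed 59 genes in this fit without pairing. Fits that paired the replicates listed 177 genes with all 9 libraries and 826 with only the 6 of wild type and pil1, and each called 1 gene, PIL1. With no gene changed, a share of 0.05 of tested genes is due on average, which 59 and 177 fall below and 826 exceeds. Genes are not independent, so these counts are no test. LSP1, the close paralog of PIL1 and the other main eisosome protein, had 26600 ± 3200 normalized reads in pil1 and 29700 ± 5540 in wild type (log2 fold change -0.15, SE 0.19, not called). Other eisosome genes were likewise not called, among them EIS1 at -0.21 (SE 0.26), the tetraspan membrane protein gene SUR7 at -0.08 (SE 0.37), SEG2, the paralog of SEG1, at -0.13 (SE 0.12), and PUN1 at 0.30 (SE 0.16). In the fit without pairing, the 95% confidence interval of the fold change lay within 2-fold of no change for 5632 genes, or 95.7%, and within 1.5-fold for 82.1%. Counting tests on the recovered reads gave 1 gene with edgeR and 2 with DESeq2, the second being THI4 of thiamine synthesis at a log2 fold change of -0.54, which limma did not call (adjusted p = 0.422 by limma). At an unadjusted p under 0.05 they listed 57 and 79 genes.

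Camera at the preset correlation called small shifts of gene lists in pil1, with 4 lists higher and 14 lower of 39 tested, although no list member passed the test over all genes. Fry called 0 lists, with or without pairing. An estimated correlation left 1 list, and 0 in the fit that paired the replicates, so these shifts depend on the preset correlation. The cell wall list, 43 genes of wall proteins and targets of the wall integrity pathway, was higher by a median log2 fold change of 0.16 (adjusted p = 1.44e-07 by limma's camera, adjusted p = 0.667 with an estimated correlation). Among its members, KDX1, a kinase-related gene of that pathway, had 2180 ± 270 normalized reads against 1520 ± 213, and the wall protein gene PST1 had 13300 ± 1580 against 9490 ± 1640. The 36 general stress genes under Msn2 and Msn4 were lower by a median of -0.20 (adjusted p = 2.81e-08 by camera, adjusted p = 0.667 with an estimated correlation), and the catalase gene CTT1 had 33200 ± 5890 normalized reads against 43300 ± 10900. The 5 genes specific to MATα cells were lower by a median of -0.18 (adjusted p = 1.35e-07 by camera). Theirs was the 1 list still called with an estimated correlation (adjusted p = 0.0431), and it was not called with an estimated correlation in the fit that paired the replicates (adjusted p = 0.363). MF(ALPHA)1, the gene of the α-factor pheromone, had 5130 ± 210 normalized reads in pil1 and 7360 ± 1020 in wild type. It was the 1 member of that list lower when adjusted over the list alone. The 17 haploid and pheromone response genes were lower by a median of -0.09 (adjusted p = 1.85e-06 by camera, adjusted p = 0.277 with an estimated correlation). These 4 lists kept their calls in all 22 other settings that kept the preset correlation.

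The other 14 list calls in pil1 each ended or turned when some single library was left out, which also broke the pairing of wild type and pil1 libraries. When both libraries of a pair were left out, a choice made after seeing the data, 10 of these 14 calls ended or turned in at least 1 of the 3 cases and 4 did not, those of the cytosolic ribosome, tricarboxylic acid cycle, glycolysis and cell cycle lists. The 138 cytosolic ribosomal protein genes had a median of 0.16 (adjusted p = 1.41e-25 by camera, adjusted p = 0.667 with an estimated correlation), and were not called without wild type replicate 2 alone (adjusted p = 0.129). The 67 ribosome biogenesis genes had a median of 0.14 (adjusted p = 2.29e-06, adjusted p = 0.794 with an estimated correlation), which turned to -0.12 without wild type replicate 2 (adjusted p = 2.28e-05) and to -0.03 without pil1 replicate 1 (adjusted p = 0.404), and the list was not called without the pair numbered 2 (adjusted p = 0.298). The median of these genes, relative to the wild-type mean, was 0.39, -0.52 and 0.14 in wild type replicates 1 to 3 and 0.51, -0.17 and 0.13 in pil1. The 17 glycolysis genes had a median of -0.24 (adjusted p = 1.4e-05, adjusted p = 0.667 with an estimated correlation), and were not called without pil1 replicate 2 (adjusted p = 0.28). The 17 eisosome genes had a median of -0.09 (adjusted p = 0.0171, adjusted p = 0.776 with an estimated correlation), and were not called without wild type replicate 2 (adjusted p = 0.706), wild type replicate 3 (adjusted p = 0.0587), pil1 replicate 1 (adjusted p = 0.739) or the pair numbered 2 (adjusted p = 0.401). The 27 cell cycle genes had a median of -0.07 (adjusted p = 0.000485, adjusted p = 0.667 with an estimated correlation), and were not called without wild type replicate 2 (adjusted p = 0.281) or pil1 replicate 1 (adjusted p = 0.0524). DSE1, a gene of daughter cell separation, was the 1 member of that list lower when adjusted over the list alone, at 480 ± 33.9 normalized reads against 651 ± 60.8.

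In the fit that paired the replicates the respiratory chain list was no longer called (adjusted p = 0.045 without pairing, adjusted p = 0.0524 with it), and the osmotic stress list was gained (adjusted p = 0.138 without pairing, adjusted p = 0.032 with it, adjusted p = 0.723 with an estimated correlation in the paired fit). The 44 respiratory chain genes had a median of -0.04 in pil1 (adjusted p = 0.794 with an estimated correlation), and were not called without wild type replicate 1 (adjusted p = 0.266) or 3 (adjusted p = 0.514), or without pil1 replicate 1 (adjusted p = 0.252) or 2 (adjusted p = 0.89), nor without the pair numbered 1 (adjusted p = 0.436) or 2 (adjusted p = 0.372).

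The triple mutant differed from wild type across much of the genome, and genes of fermentation, sugar uptake and iron retention were among those with the largest changes. PDC5 and PDC1, which encode pyruvate decarboxylases of ethanol formation, were 192-fold and 43.9-fold lower, at 495 ± 49.5 and 12800 ± 3260 normalized reads against 96800 ± 23400 and 551000 ± 82600 in wild type. HXT1, a low-affinity glucose transporter gene, was 76.1-fold lower (296 ± 93.9 against 23700 ± 10400), and ENO2, an enolase gene with a 94.8% identical copy in ENO1, was 22-fold lower. HXT6, a high-affinity hexose transporter gene, was 127-fold higher (127000 ± 38200 against 970 ± 63.1), but its coding sequence is 99.8% identical to that of HXT7 and reads of the pair are uncertain. FIT2 and FIT3, cell wall mannoprotein genes that help retain siderophore iron, rose 78.4-fold and 34.3-fold, with FIT2 at 38000 ± 26500 normalized reads against 414 ± 104.

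Further large rises were those of YGR067C, a putative zinc-finger gene, at 61.3-fold, YIG1 at 48.2-fold, the respiratory growth genes RGI1 and RGI2 at 33.1-fold and 32.2-fold, and ACH1, which encodes a CoA transferase of acetate metabolism, at 32.7-fold. Without triple mutant replicate 1 the rise of YGR067C was 40.8-fold and that of RGI2 18.3-fold. Further large falls were those of the G1/S gene TOS4 at 21.2-fold, of ARO10 and ARO9 of aromatic amino acid breakdown at 20.2-fold and 19.1-fold, and of AGA2, a mating adhesin subunit, from 238 ± 34.2 to 11.5 ± 2.4 normalized reads. Adjusted p by limma ranged between 5.04e-08 for PDC5 and 0.000235 for RGI2 over these genes.

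In all, limma called 3586 of 5886 genes (60.9%), 1770 higher and 1816 lower, with 468 and 704 of them changed by at least 2-fold. Counts of called list members are to be read against that share. edgeR on the recovered reads called 3604 genes, of which 3560 were shared with limma. When libraries were scaled by total reads, a choice made after seeing the data, the median of all genes moved to a log2 fold change of -0.23, and the split became 1028 higher and 2380 lower. Without wild type replicate 1 and triple mutant replicate 1 together, another choice made after seeing the data, 3139 genes were called, 3000 of them shared.

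**Figure D2:**
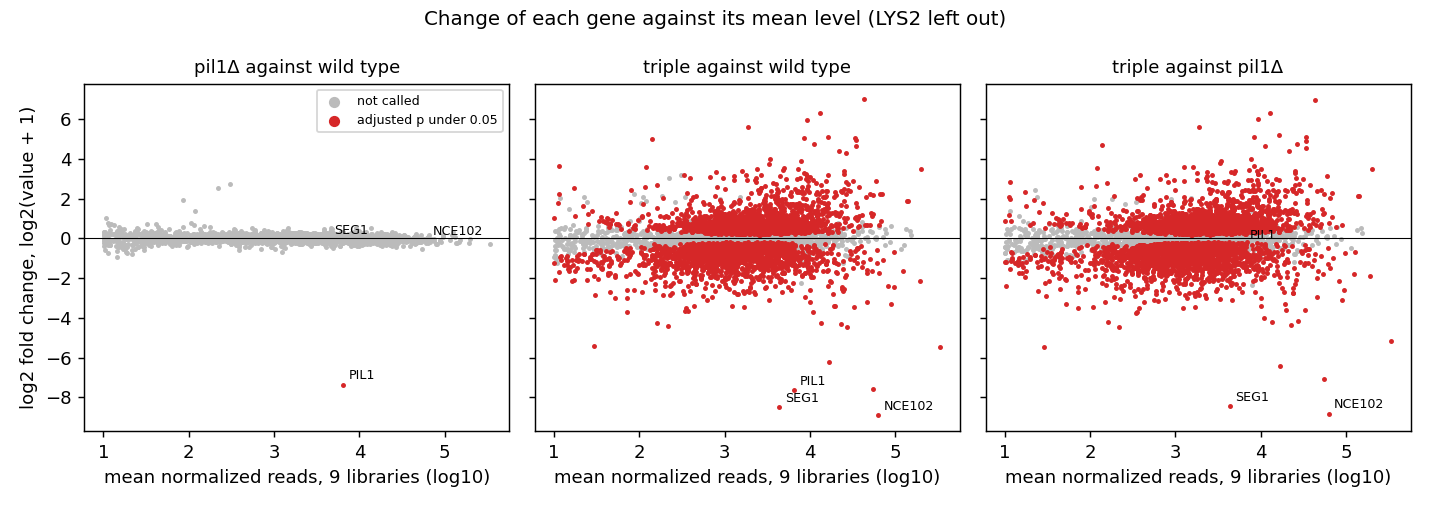
Log2 fold change of each tested gene (vertical axis) against its mean normalized reads over all libraries (horizontal axis, log scale), for pil1 against wild type, the triple mutant against wild type and the triple mutant against pil1. Limma called 1, 3586 and 3705 genes, drawn as red points, except that LYS2, which has 0 reads in 6 libraries, is left out of the panels.

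Genes of respiratory metabolism were higher in the triple mutant. Of 44 nuclear genes of the respiratory chain and ATP synthase, 43 rose and 0 fell, with 43 and 0 adjusted over the list alone, and the median log2 fold change was 2.09 (adjusted p = 2.92e-18 by camera, adjusted p = 0.47 with an estimated correlation). COX4, a subunit of cytochrome c oxidase, rose 7.8-fold from 2700 ± 166 to 21400 ± 5100 normalized reads, SDH4 of succinate dehydrogenase 7.7-fold and COR1 of the cytochrome bc1 complex 4.64-fold. Of 18 tricarboxylic acid cycle genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone). Their median was 2.21 (adjusted p = 3.33e-06 by camera, adjusted p = 0.47 with an estimated correlation), and SDH1 rose 9.4-fold, the malate dehydrogenase gene MDH1 7.06-fold and KGD1 of alpha-ketoglutarate dehydrogenase 5.94-fold. Of 72 genes in the mitochondrial ribosome list, 66 rose and 1 fell (67 and 3 adjusted over the list alone), with a median of 0.70 (adjusted p = 1.65e-12 by camera, adjusted p = 0.47 with an estimated correlation). MRPL35 rose 3.05-fold and MRPL16 2.4-fold. That list was drawn by symbol and also holds YMR31, a subunit of alpha-ketoglutarate dehydrogenase, at a log2 fold change of 2.43, and the phosphatase gene YMR1, the member that fell, at -0.56.

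Many genes for the use of ethanol and acetate were higher as well, and to different extents in the 3 libraries. Of 24 genes of gluconeogenesis, the glyoxylate cycle and ethanol and acetate use, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 2.37 (adjusted p = 0.000197 by camera, adjusted p = 0.61 with an estimated correlation). CAT8, the activator of gluconeogenic genes, rose 9.5-fold from 2290 ± 122 to 22600 ± 8020 normalized reads, and CAT2, a carnitine acetyltransferase, rose 5.34-fold. The alcohol dehydrogenase gene ADH2 had 2156, 1474 and 1513 normalized reads in triple mutant replicates 1 to 3. In wild type it had 1656, 1603 and 1735, so not every gene of ethanol use rose. Replicate 1 stood apart from the other triple mutant libraries in this group, with a list median of 4.35 against 1.31 and 1.54 in replicates 2 and 3, and the median was 1.48 without it. Replicate 1 also differed more over all genes. Its chi-square per degree of freedom was 382.8 and 300.1 against replicates 2 and 3, which gave 50.4 against each other. JEN1, a lactate and pyruvate transporter gene, had 147600, 14330 and 23020 normalized reads in the 3 libraries, and its rise was 21.3-fold, 10.6-fold without replicate 1 and 34.1-fold without replicate 2. The share of reads from mitochondrially encoded genes was 0.0204%, 0.0065% and 0.00191% in triple mutant replicates 1 to 3. It was 0.00425%, 0.00342% and 0.000622% in wild type replicates 1 to 3 and 0.00403%, 0.00342% and 0.000887% in pil1. The share thus fell with the replicate number in every strain, and replicate 1 of the triple mutant is not told apart from that order. Of 11 such genes, 0 were called in the triple mutant against wild type. Of 17 genes of glycolysis and ethanol formation, 0 rose and 16 fell, with 0 and 16 adjusted over the list alone, and the median was -2.40 (adjusted p = 1e-06 by camera, adjusted p = 0.47 with an estimated correlation). CDC19, the main pyruvate kinase gene, was 9.74-fold lower.

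**Figure D3:**
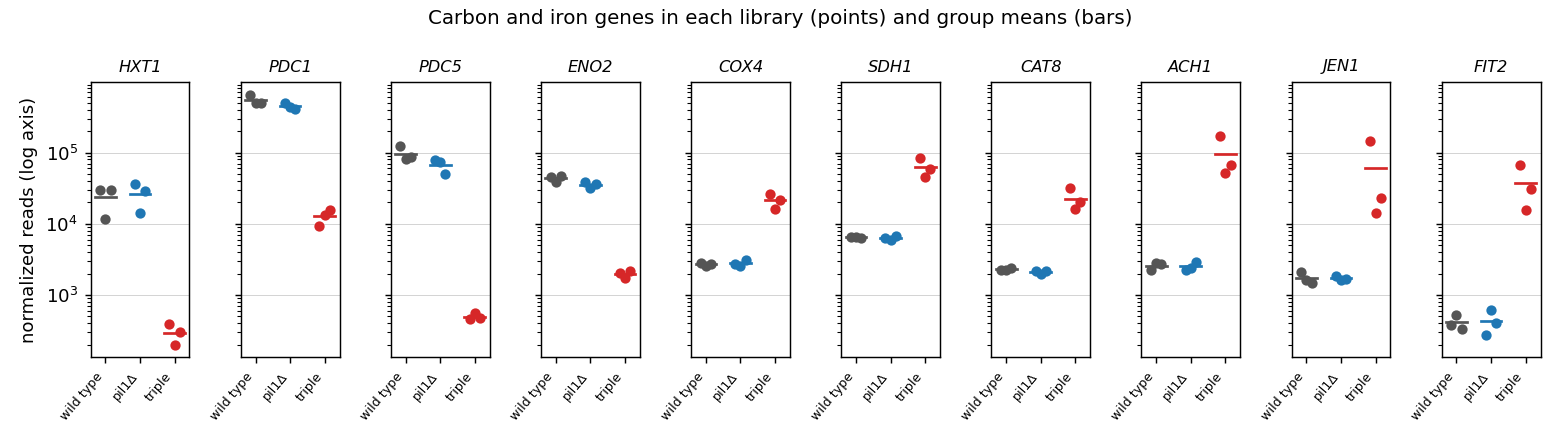
Normalized reads (vertical axis, log scale) of HXT1, PDC1, PDC5, ENO2, COX4, SDH1, CAT8, ACH1, JEN1 and FIT2 in each of the 9 libraries, 1 point per library, with bars at the group means. PDC5 averages 96800 in wild type and 495 in the triple mutant, and JEN1 reaches 147600 in triple mutant replicate 1 against 14330 and 23020 in the other two.

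Genes of cytosolic ribosomes were lower in the triple mutant. Of 138 ribosomal protein genes, 0 rose and 129 fell, with 0 and 129 adjusted over the list alone, and the median log2 fold change was -1.13 (adjusted p = 1.81e-23 by camera, adjusted p = 0.47 with an estimated correlation). RPS22A, which shares a 90.4% identical stretch with RPS22B, was 6.92-fold lower (429 ± 98.5 against 2950 ± 544), RPL14A 4.09-fold and RPP2A 3.81-fold. The symbol rule for this list also took in RPP1, a subunit of nuclear RNase P, at -0.51. Of 67 ribosome biogenesis genes, 2 rose and 31 fell (2 and 30 adjusted over the list alone), with a median of -0.64 (adjusted p = 0.00111 by camera, adjusted p = 0.754 with an estimated correlation). NOP58 of the box C/D snoRNP was 4.51-fold lower and GAR1 of the box H/ACA snoRNP 2.71-fold.

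Genes of the iron regulon, of the Msn2 and Msn4 stress response and of entry into stationary phase were higher, and 3 other stress lists did not pass the test. Of 26 genes under the iron regulators Aft1 and Aft2, 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.14 (adjusted p = 3.33e-06 by camera, adjusted p = 0.47 with an estimated correlation). SMF3, a vacuolar iron transporter gene, rose 2.54-fold and the multicopper oxidase gene FET5 2.22-fold. The median of the iron list, relative to the wild-type mean, was 1.52, 0.837 and 0.985 in triple mutant replicates 1 to 3. Of 36 general stress genes under Msn2 and Msn4, 21 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.65 (adjusted p = 0.000112 by camera, adjusted p = 0.61 with an estimated correlation). The glucokinase gene GLK1, which overlaps YCL042W on the same strand by 106 bases, rose 4.72-fold, and SOD2, the mitochondrial superoxide dismutase, rose 2.83-fold. Of 19 genes induced on entry into stationary phase, 14 rose and 2 fell, with 14 and 2 adjusted over the list alone, and the median was 1.39 (adjusted p = 0.000697 by camera, adjusted p = 0.47 with an estimated correlation). HSP30, a plasma membrane stress protein gene, rose 11.2-fold and SPG1 10.3-fold, whereas the polyubiquitin gene UBI4 and the vitamin B6 pathway gene SNO1 fell. Of 19 heat shock chaperone genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 0.109 by camera), of 17 osmotic stress genes, 8 rose and 6 fell (8 and 6 adjusted over the list alone, adjusted p = 0.585 by camera), and of 24 oxidative stress genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone, adjusted p = 0.899 by camera). The heat shock chaperone list, with a median of 0.40, was called without wild type replicate 3 (adjusted p = 0.037) or triple mutant replicate 1 (median 0.55, adjusted p = 0.043), against adjusted p = 0.754 with an estimated correlation over all libraries. The median of the oxidative stress list lay just below 0 and its mean was 0.17. HSP30 was the gene with most reads in the 3 triple mutant libraries, at 1.3% to 2.63% of reads, and PDC1 was in the other 6, at 1.86% to 2.87%.

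Among the remaining eisosome genes, 9 of 17 rose and 1 fell, with 9 and 1 adjusted over the list alone. This is near the 60.9% called over all genes. LSP1 rose 2.22-fold from 29700 ± 5540 to 65500 ± 9260 normalized reads (adjusted p = 0.000639 by limma). MDG1 rose 3.28-fold, the SUR7-family gene YNL194C 4.88-fold, EIS1 2.1-fold, FMP45 2.11-fold, and the kinase gene PKH2, a homologue of mammalian PDK1, 1.86-fold. SLM2, RFS1 and PKH3 rose by 1.52-fold, 1.42-fold and 1.29-fold. PUN1, a membrane protein gene of the same compartment, was 2.61-fold lower. SUR7, SEG2, FHN1, PKH1, SLM1, PST2 and YCP4 were not called, although SLM1 was called without wild type replicate 2 (log2 fold change 0.56, adjusted p = 0.00886 by limma). The list median was 0.37 (adjusted p = 0.0363 by camera, adjusted p = 0.61 with an estimated correlation), and the list was not called without wild type replicate 1 (adjusted p = 0.0966), without triple mutant replicate 2 (adjusted p = 0.0602) or without triple mutant replicate 3 (adjusted p = 0.0503). Nor was it called without wild type replicate 1 and triple mutant replicate 1 together (adjusted p = 0.0569) or with the GC and length trend removed (adjusted p = 0.0682). RFS1 and PKH3 were not called when libraries were scaled by total reads, and FMP45 was not called without wild type replicate 1 and triple mutant replicate 1 together (adjusted p = 0.083).

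Cell wall genes were mostly lower, in contrast with the small upward shift that camera called in pil1 at the preset correlation. Of 43 genes, 8 rose and 29 fell, with 8 and 29 adjusted over the list alone, and the median was -0.85 (adjusted p = 0.000312 by camera, adjusted p = 0.47 with an estimated correlation). The wall mannoprotein gene CWP2 was 13.3-fold lower (1090 ± 230 against 14400 ± 2400), the glucanase gene EXG1 9.18-fold, and SLT2, the kinase of the wall integrity pathway, 3.64-fold. In the direct test of the triple mutant against pil1, 8 of these genes rose and 32 fell, with 8 and 32 adjusted over the list alone (adjusted p = 9.74e-05 by camera, adjusted p = 0.449 with an estimated correlation). Of 28 ergosterol synthesis genes, 5 rose and 16 fell (5 and 16 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.0101 by camera, adjusted p = 0.47 with an estimated correlation), and the methyl oxidase gene ERG25 was 3.43-fold lower. Of 27 genes of sulfate assimilation and methionine synthesis, 3 rose and 14 fell (3 and 14 adjusted over the list alone), with a median of -0.53 (adjusted p = 0.0214 by camera, adjusted p = 0.622 with an estimated correlation). SAM2, an S-adenosylmethionine synthetase gene, was 5.27-fold lower and CYS3, of cystathionine gamma-lyase, 4.48-fold lower. The methionine list was not called without triple mutant replicate 2 (adjusted p = 0.051).

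Mating genes were lower in the triple mutant. All 5 MATα-specific genes fell, with 0 and 5 adjusted over the list alone, and the median was -0.56 (adjusted p = 0.00969 by camera, adjusted p = 0.47 with an estimated correlation). MF(ALPHA)1 was 3.38-fold lower and the agglutinin gene SAG1 2.36-fold. Of 17 haploid and pheromone response genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone), with a median of -0.84 (adjusted p = 0.00175 by camera, adjusted p = 0.47 with an estimated correlation), and the pheromone arrest gene FAR1 was 6.94-fold lower. The 7 MATa-specific genes, markers of the opposite mating type, gave 1 higher and 5 lower (1 and 6 adjusted over the list alone), with a median of -1.25 (adjusted p = 0.0228 by camera, adjusted p = 0.47 with an estimated correlation). STE2, the α-factor receptor gene, was 2.62-fold lower. Of 29 genes of mRNA decay, 12 rose and 0 fell, against 60.9% called over all genes (10 and 0 adjusted over the list alone). The list was called at a median of 0.14 (adjusted p = 0.0356 by camera, adjusted p = 0.47 with an estimated correlation). That call was lost without triple mutant replicate 2 (adjusted p = 0.0519) and when libraries were scaled by total reads, where the median was -0.08.

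**Figure D4:**
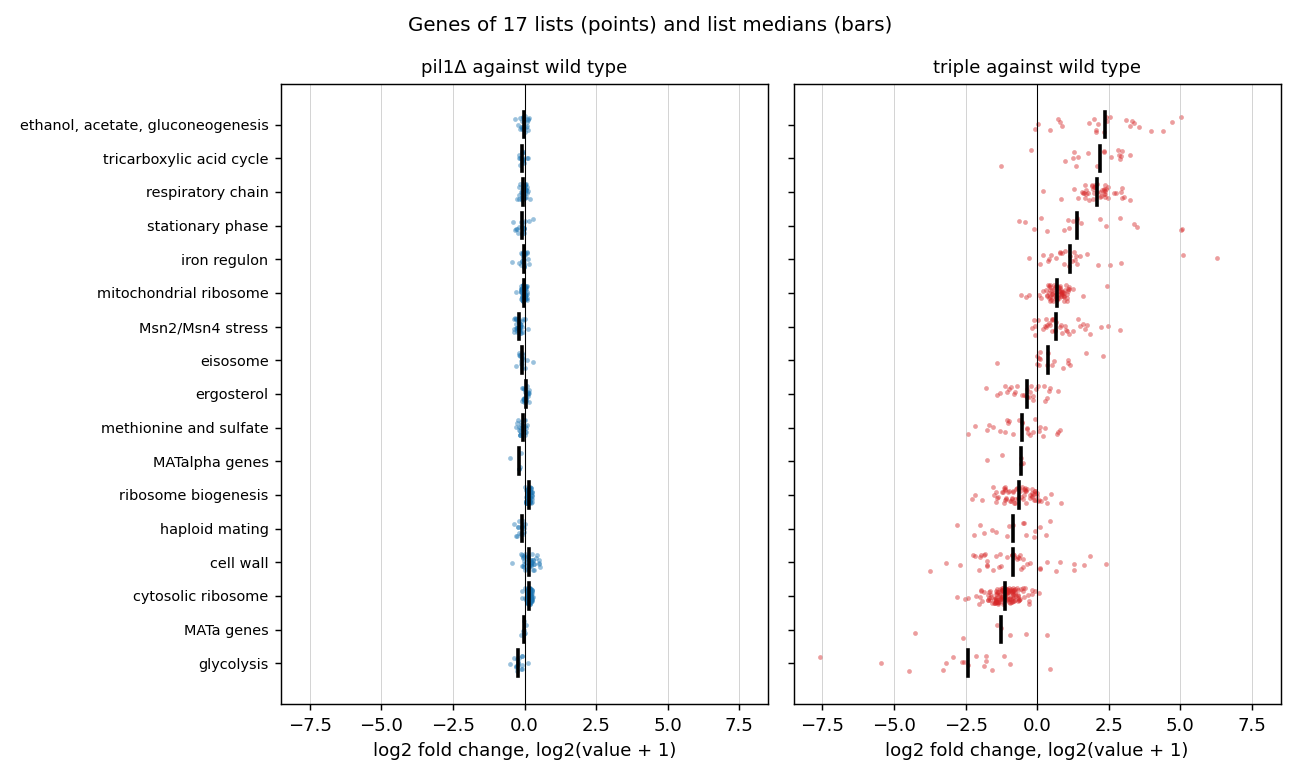
Log2 fold change on the log2(value + 1) scale (horizontal axis) of the members of 17 gene lists (vertical axis), for pil1 against wild type and the triple mutant against wild type in separate panels, with 1 point per gene and bars at list medians. The respiratory chain list has a median of 2.09 and the glycolysis list of -2.40 in the triple mutant, against -0.04 and -0.24 in pil1.

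Genes beside the loci that differ between the strains were examined because a deletion cassette can alter its neighbours. None was called in pil1. In the triple mutant 3 of 8 were higher and 1 lower (3 and 1 adjusted over the list alone), against 60.9% called over all genes, and camera did not call the list (adjusted p = 0.453). SUE1, beside NCE102, had a log2 fold change of 1.29 (SE 0.14), PDC6 and RPL11B, which flank PIL1, had 1.62 (SE 0.23) and -1.13 (SE 0.23), and YPR148C, on the other side of NCE102, had 0.53 (SE 0.11), all called by limma. RPL11B is 97% identical to RPL11A. YPR148C was not called when libraries were scaled by total reads (adjusted p = 0.102). YMR085W, PDL32, TKL2 and RAD16 were not called, although YMR085W, beside SEG1, was called without wild type replicate 1 (log2 fold change -0.63, adjusted p = 0.0451 by limma) and without triple mutant replicate 1 (-0.66, adjusted p = 0.0252).

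The direct comparison of the triple mutant with pil1, which asks what the further genotype differences add to loss of PIL1, gave the same leading genes as the comparison with wild type, except that HXT7 took the place of RGI2. HXT6 was 124-fold higher, FIT2 78.7-fold, YGR067C 63.8-fold, YIG1 48.3-fold, FIT3 36.5-fold, RGI1 34.1-fold, ACH1 33.7-fold and HXT7 29.7-fold. PDC5 was 133-fold lower (495 ± 49.5 against 67200 ± 14600 normalized reads), HXT1 84.7-fold, PDC1 35.9-fold, TOS4 21.9-fold, ARO10 20.4-fold, ARO9 18.8-fold, AGA2 18.7-fold and ENO2 17.9-fold. LSP1 was 2.46-fold higher (65500 ± 9260 against 26600 ± 3200, adjusted p = 0.000283 by limma). PIL1 itself, deleted in both, was not called (log2 fold change -0.28, SE 0.12, adjusted p = 0.0588 by limma), but the call depended on the setting. It was called at an adjusted p of 0.0243 without wild type replicate 1, 0.0413 without wild type replicate 1 and triple mutant replicate 1 together, 0.0297 with the GC and length trend removed, and 0.00711 with scaling by total reads (log2 fold change -0.54).

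The triple mutant and pil1 differed at 3705 of 5886 genes by limma, 1813 higher and 1892 lower, with 520 and 774 changed by at least 2-fold. With scaling by total reads the median of all genes moved to -0.27 and the split became 1023 higher and 2574 lower. In both comparisons of the triple mutant, 1698 genes were called higher and 1752 lower, and 0 were called in opposite directions. Both comparisons use the same triple mutant libraries, so this overlap is not independent evidence. Simulated libraries in which pil1 equalled wild type and the triple mutant kept its observed differences shared 1722 ± 16.2 and 1783 ± 16 genes (SD, 50 simulations), and libraries in which no group differed shared 0 and 0. The observed differences already hold sampling noise, and the libraries were drawn without the pairing of wild type and pil1. The simulated counts are therefore no test of whether pil1 equals wild type. With no group differing, the threshold itself allows few shared calls. Camera called 17 lists, among them the respiratory chain genes at a median of 2.14 with 43 of 44 higher (43 adjusted over the list alone), glycolysis at -2.13 with 15 of 17 lower (15 adjusted over the list alone) and cytosolic ribosomal proteins at -1.29 with 130 of 138 lower (131 adjusted over the list alone). With an estimated correlation 0 lists were called (the smallest adjusted p = 0.449 with an estimated correlation), as in the comparison with wild type (the smallest adjusted p = 0.47 with an estimated correlation). Fry, which compares a list with no other genes, called 27 lists against pil1 and 28 against wild type. Most genes were called in both comparisons, so calls by fry do not set a list apart from other genes. The autophagy list was called with a median of 0.36 (adjusted p = 0.0328 by camera, adjusted p = 0.579 with an estimated correlation). Of its 30 members, 16 were higher and 4 lower (16 and 4 adjusted over the list alone), against 62.95% called over all genes. The list was not called without pil1 replicate 1 (adjusted p = 0.0527) or with scaling by total reads (adjusted p = 0.091). Against wild type the same list had 15 higher and 3 lower (15 and 3 adjusted over the list alone) and a median of 0.26, short of the threshold (adjusted p = 0.0546 by camera, adjusted p = 0.61 with an estimated correlation), and was called without wild type replicate 2 (adjusted p = 0.0224), without the filter on low values (adjusted p = 0.0405) and with the GC and length trend removed (adjusted p = 0.0349). The heat shock chaperone list was short of the threshold against pil1 (12 higher and 3 lower of 19, 12 and 3 adjusted over the list alone, adjusted p = 0.0576 by camera, adjusted p = 0.666 with an estimated correlation) and was called in several alternatives, at an adjusted p of 0.0266 without triple mutant replicate 1, 0.0414 and 0.0497 without wild type replicates 3 and 1, 0.0214 without wild type replicate 1 and triple mutant replicate 1 together, 0.0481 without the filter on low values and 0.0277 with scaling by total reads.

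Set against the shared wild type, PIL1 was the 1 gene called both in pil1 and in the triple mutant. Across 5880 genes, which are not independent replicates, the fold changes had a correlation of -0.17, whereas unchanged groups simulated with 1 shared wild type of 3 libraries gave 0.50 ± 0.03 (SD, 100 simulations). The covariance was -0.0211 against 0.0239 ± 0.0025 in the simulations, and 38% of genes had the same sign against 66.7%. Without wild type replicate 2 the correlation was 0.0856. The 3 wild type libraries are too few to be split into sets of at least 2. The simulated groups were drawn independently, without the pairing of wild type and pil1 libraries, and such pairing lowers the covariance that a shared wild type adds, so the simulated values are too high for these libraries by an amount not estimated here. The simulated triple mutant was also left unchanged, whereas its measured log2 fold changes had an SD of 0.973 over all tested genes, against 0.165 in pil1. Changes of that size lower the correlation and same-sign share that a shared wild type gives. The simulated 0.50 and 66.7% are thus not no-change values for these libraries, and no conclusion is drawn from them.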

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

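The tests chosen only after the data were seen are those with edgeR, DESeq2, total-read scaling, wild type 1 and triple mutant 1 left out together, each wild type and pil1 pair left out, the block with only the groups compared, and the GC and length trend. In pil1 against wild type, every alternative called PIL1, and the count of called genes was 1 in all but DESeq2, where it was 2, both lower and both also called in the triple mutant. In the triple mutant, leaving out each library gave 3195 to 3516 calls against wild type and 3263 to 3758 against pil1. Total-read scaling gave 1028 and 1023 genes higher. The deposited scaling and TMM scaling are built to leave most genes unchanged. They gave a median log2 fold change of -0.00796 and -0.00418 against wild type, where total-read scaling gave -0.234. The near-even split of higher and lower genes therefore depends on the scaling, and which scaling is right was not tested.

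Counts of called lists depended on the correlation assumed. An estimated correlation gave 1 list in pil1, 0 in the triple mutant against wild type and 0 against pil1, and fry gave 0, 28 and 27. Leaving out each library gave 9 to 18 lists in pil1, with 9 without pil1 replicate 1. Leaving out the pairs numbered 1 to 3 gave 16, 13 and 21. Over left-out libraries the list medians in pil1 ranged for eisosome genes from -0.18 to 7.6e-05, for methionine genes from -0.151 to 0.0174 (also 0.0174 without wild type 1 and triple mutant 1 together), for heat shock chaperones from -0.168 to -0.00642, for ribosome biogenesis from -0.12 to 0.345, and for the mitochondrial ribosome from -0.055 to 0.0137, and 0.0165 without the pair numbered 1. The correlation of the pil1 and triple mutant fold changes ranged from -0.2 to 0.0856 over left-out libraries, and was -0.227 with the transformed table, -0.209 with a pseudocount of 5, -0.204 with a minimum mean of 50 and -0.0887 with no filter. The cause of these changes was not tested.

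With the replicate block, pil1 kept its count of 1 and its list count of 18. Correlations of deviations between same-numbered libraries were 0.0499, 0.191 and 0.362 for wild type and the triple mutant and 0.0694, 0.237 and 0.439 for pil1 and the triple mutant, so those share only a number by the rule used, although 9 of 9 libraries correlated best with their own number in the other groups, a hint from the data. The block moved the counts to 4024 and 4162, of which 3562 and 3686 were shared with the fit without it. In pil1 against wild type it changed no call beyond the lists given with the results. In the triple mutant it added 2 named genes, SLM1 (adjusted p = 0.0302) and ILV2, and took away LEU9 against wild type. The block alone kept the call of the eisosome list there (adjusted p = 0.0338 by camera). Removal of the GC and length trend ended that call with or without the block (adjusted p = 0.0775 with both). Against pil1 the block added 5 named genes, PIL1 (adjusted p = 0.0387) and SLM1 among them, and the mRNA decay list (adjusted p = 0.0446, adjusted p = 0.638 with an estimated correlation in the same fit).

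Of the named genes called in the triple mutant, 8 of 171 against wild type and 12 of 169 against pil1 lost the call in some alternative, and 0 reversed. Named genes were chosen mainly for a small p or a large change, which favours a kept call, so these counts do not hold for all calls. Of all calls, total-read scaling kept 2844 of 3586 against wild type (79.3%) and 2915 of 3705 against pil1 (78.7%). The median standard error of a fold change was 0.128 on the log2 scale in the fit without pairing, and 329 genes with few reads were not tested.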

Other observations

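The tests chosen only after the result was seen are those of the 3 patterns weighed in this part and the paired fit of 6 libraries, whereas the gene lists and the count of other splits were planned. Several gene groups not described above held changed members in the triple mutant, most of them in both directions, and camera did not call these lists. Over all tested genes 60.9% were called, so called members alone do not set a group apart. Of 21 hexose transport genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.188 by camera), and the glucose sensor gene SNF3 rose 4.96-fold. Of 9 core histone genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, adjusted p = 0.129 by camera), with HTA2 and HTB2 lower by 6.2-fold and 5.72-fold, where HTA2 is 93.7% identical to HTA1. Of 27 cell cycle genes, 8 rose and 14 fell (8 and 14 adjusted over the list alone, adjusted p = 0.188 by camera). RNR1, a ribonucleotide reductase gene, was 10.7-fold lower and the G1 cyclin gene CLN2 3.81-fold, whereas the daughter-specific genes DSE4 and DSE1 were 2.73-fold and 2.48-fold higher. Of 10 arginine synthesis genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.154 by camera), with ARG5,6 lower by 2.97-fold. Of 20 amino acid permease genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.613 by camera), with GAP1 lower by 3.56-fold and ALP1 higher by 3.34-fold. The median of the permease list, relative to the wild-type mean, was 0.618, -0.112 and -0.00418 in triple mutant replicates 1 to 3.

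In pil1, the fit that paired the 6 wild type and pil1 libraries left 7 genes at an adjusted p of 0.0593 by limma, short of the threshold, each moving the same way in 3 of 3 pairs. A small paired p from 3 pairs already favours such agreement, so it is no added support. The cell wall genes CRH1, PIR3 and PST1 had log2 fold changes of 0.41, 0.51 and 0.49, KDX1 had 0.52 and the steryl ester hydrolase gene YEH1 0.42, while THI4 had -0.54 and the wall mannoprotein gene TIP1 -0.38. An unadjusted p under 0.05 was reached by 826 genes in that fit, against 116 in the same 6 libraries without pairing, and by 177 and 59 genes with and without pairing in the fit of 9 libraries.

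The first pattern weighed was that of higher respiratory chain and lower glycolysis genes in the triple mutant. Scaling of the libraries cannot move the gap between the 2 list medians within a library, and this gap was -3.73 to -3.23 in the 6 other libraries and 0.292 to 1.54 in the triple mutant, 3.52 apart on the log2 scale, which argues against scaling as the source. Strain differences outside the 3 deletions remain open, since LYS2 differs and 2 genes near the left end of chromosome III, YCL075W and YCL074W, had 0 reads in the triple mutant against totals over 3 libraries of 55 and 150 reads in wild type and 50 and 158 in pil1. That count took genes with a mean of at least 10 reads in the strains that have them, a threshold raised after a mean over 3 had given 6 genes. Different stages of growth at harvest may also contribute, because the stationary phase list was higher by 1.39, and an effect of the deletions themselves is not told apart from either by these strains.

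The second pattern was that of reads counted on the deleted genes. Wild type RNA mixed into the triple mutant libraries at 1 share would leave the 3 genes at the same percent of wild type, but the ratio of PIL1 to NCE102 was 3.25, 1.96 and 2.1, which argues against it as the source of all 3. It stays open as a source for SEG1 and NCE102, because SEG1 had few reads and kept 0.206% and 0.21% in replicates 2 and 3, near the 0.242% and 0.248% of NCE102, but 0.412% against 0.144% in replicate 1, a ratio of 2.86. Reads assigned to the wrong library are argued against by LYS2, which had 0 reads in the 6 wild type and pil1 libraries: if the NCE102 level in the triple mutant, 0.218% of that in the other strains, came from such reads, the same share of LYS2 would predict 175. Reads of the paralog LSP1 are argued against too, because the level on PIL1 in the triple mutant was 0.82 times that in pil1 while LSP1 was 2.46 times as high, and transcription of sequence left at the loci was not tested.

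The third pattern was a gap in wild type replicate 1 at the left end of chromosome I. SEO1, YAL065C, YAL064W-B and TDA8, between positions 7235 and 13743, had 0, 1, 5 and 0 reads there, against at least 270, 74, 111 and 219 in each other library, while FLO9 at 24000 to 27968 had 1437 reads. Such a loss was found for 4 genes in this library and 0 in the other 8, which argues against chance at this depth. A lost segment in that culture is a candidate explanation that stays open, because the genes nearer the chromosome end average at most 1.38 reads in the other libraries. No biological explanation from the design was tested for this pattern.

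For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave a count as large. The real counts were 1 for pil1 against wild type, 3586 for the triple mutant against wild type and 3705 against pil1, and the highest of the other splits was 0 in each. The 1 call in pil1 is the deleted gene PIL1, so the genotype fixed that outcome. For the triple mutant, mixed splits put strains that differ across much of the genome on both sides, which widens the spread within each side. These counts therefore add no support to the calls. In pil1, where numbers pair the libraries, 4 splits part all 3 pairs, the real one included, and the others of these called 0 genes. The other 6 splits part 1 pair and also called 0 genes, though up to 802 genes reached an unadjusted p under 0.05 there.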
